A study of Mus musculus with 6 samples.

How the data were processed

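Total RNA was taken from the hearts of 6 mouse embryos late in gestation, per the labels' protocols, and 50 ng of each was amplified linearly with a NuGEN Ovation kit before hybridisation to Affymetrix mouse 430A v2 arrays. Titles, descriptions and the series' design text name the tissue as heart, while the source label names thorax, and heart is used here. The labels give no litter, sex, processing date or batch. The deposited values are RMA intensities, 1 per probe set and array, which the authors made with robust multi-array analysis in Bioconductor per the series' design text and the submitters' processing notes. RMA corrects the background, quantile-normalises the arrays and summarises the probes of each probe set. The deposited intensities run on a linear scale rather than in log2, as their range shows, and the version of RMA and the chip definition are not given in the sources used here. The linear scale was taken to log2 for all tests, with no further scaling. RMA gives no detection call, so low values could not be told from background, and differences of probe sets near the floor are understated.

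The table held 22690 probe sets, of which 64 Affymetrix controls were left out, and 22626 were tested. Probe sets were paired with genes by GEO's platform annotation, which names 1 gene for 20380 of the tested probe sets, several for 691 and none for 1555. Only probe sets with 1 gene were named. Entrez identifiers of 20351 matched the RefSeq gene table of assembly GRCm38.p6, 0 symbols had to be updated, and 12393 genes were measured. As the files name no genome build, the gene table was used for names and for the order of neighbouring genes only.

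Knockout and control arrays were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes over all 6 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Positive differences are higher in the knockout. The protocols speak of 3 hearts per genotype, and whether embryos shared a litter is not stated, so that p-values measure the spread between these samples. No array pair was a duplicate, since the most alike pair differed by an SD of 0.28 on the log2 scale. Genes for the text were chosen by a rule fixed before the data were examined. It takes Rbm15, the 12 largest rises and the 12 largest falls among probe sets that pass, do not overlap between groups and name 1 gene, 1 per gene, and from each gene list up to 4 members that pass, or up to 2 with the smallest unadjusted p where none does. For many lists in which no member passed, the members so taken are not named in the text. Other genes named were chosen after their values were seen, and among them are Atf4, Ddit3, Mettl3, Tnnt2, Ifit1, Alb, Scgb1a1, Xist, Hbb-b2, Hbb-y, Hba-x, Phgdh, Slc7a5, Trib3, Pou2af1 and the genes that passed by a dimmer probe set.

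In the same way 43 gene lists were fixed in advance, covering cardiac programmes, signalling, metabolism, stress, RNA methylation, blood cells and tissues next to the heart. Each was tested with camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene, the one with the highest mean. Lists of fewer than 5 measured genes would not have been tested, and all 43 had more. Counts of members are given over all probe sets and adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. Fry's mixed test asks whether members differ at all, in either direction, and not whether they differ more than genes outside the list. Median, mean and camera's direction differed in sign for cardiac transcription factors, mitosis, vascular smooth muscle, erythroid cells, megakaryocytes, cartilage and bone, neurons, skin and sex-linked genes, none of which passed camera. The 3' minus 5' difference of the Gapdh and Actb control probe sets was compared by an exact two-sided permutation test over the 6 arrays, whose smallest p is 0.1.

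The scripts were tested on simulated arrays of 22626 probe sets with the spread of the real ones, each drawn independently with normal noise. Of 321 probe sets changed 1.5-fold 22.4% were recovered, of 340 changed 2-fold 58.5%, and of 339 changed 4-fold 91.7%, all with the right sign, and 26 of 608 calls were false. For the list test, with genes simulated as independent, 39 of 40 lists shifted by 0.5 on the log2 scale were recovered and 0 of 109 others were called. Real genes of a list are correlated between arrays, which both simulations leave out, so their rates need not hold for the real arrays.

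Alternatives fixed beforehand were filters on low values (a mean log2 of at least 6, or the upper 50%), quantile normalisation, median centring, eBayes with a trend or robust, an unmoderated test, array weights, other choices of probe sets per gene, Xist and the Gapdh difference as covariates, a minimum of 1.5-fold, and each array left out in turn. A liver score, the mean of Alb, Afp, Apoa1, Apoa2 and Ttr, as a covariate, the liver score with its square, the fit without controls 4 and 6, and the Gapdh difference with each array left out were added after the data were examined. Quantile normalisation moved the median difference of all probe sets by 0.02 and median centring by 0.03. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.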

Results

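Gene expression was measured in 6 hearts of mouse embryos late in gestation, shortly before birth. In 3 of them both copies of Rbm15, which the labels call Ott1, were null. The other 3 hearts carried 1 null and 1 wild-type copy and served as controls. Rbm15 is an RNA-binding protein of the Spen family that guides the m6A methyltransferase complex to its target RNAs. All embryos carried the Sox2-cre transgene, which deletes floxed alleles in the epiblast and so throughout the embryo proper. Each heart was hybridised to its own Affymetrix 430A v2 array, on which 22626 probe sets other than Affymetrix controls were tested. The arrays had median intensities between 109 and 116. Arrays of the same group differed from each other by an SD of 0.28 to 0.48 on the log2 scale over all probe sets, and arrays of different groups by 0.34 to 0.53. Principal components were taken over the probe sets with a mean log2 of at least 6 only. The first held 41.3% of their variance, with the knockout arrays at -9.77, -28.5 and -11.3 and the controls at 23.6, 7.72 and 18.2. The small number of arrays limits the precision of every value.

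The comparison asks which transcripts of the late embryonic heart differ when Rbm15 is missing. Rbm15 itself, measured by 1 probe set, fell by 6.31 on the log2 scale (SE 0.20, limma adjusted p = 0.000245). Its level was 2.42 ± 0.36 in the knockout hearts and 8.72 ± 0.20 in the controls (log2, mean ± SD, n = 3 each), and each of the 3 knockout arrays lay below each control. The knockout mean stood at the 8.1 percentile of all probe sets, near the floor of the arrays, so that the 79.1-fold difference is bounded by that floor. Whether the probe set lies inside the deleted part of the gene is not given in the sources used here.

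Besides the target, single genes of several kinds differed between the knockout hearts and the controls. The embryonic beta-like globin Hbb-bh1 rose 16.5-fold, the amino acid transporter gene Slc6a17 fell by 3.17 on the log2 scale, and the interferon-induced protease Usp18 fell by 3.13. In all, 264 probe sets passed an adjusted p of 0.05 in limma, 116 higher and 148 lower in the knockout, and they named 208 genes. At an unadjusted p of 0.05, 3559 probe sets passed, 15.73% of those tested where 5% are expected by chance. The values of the 2 groups did not overlap for 22.88% of all probe sets, where chance gives 10%, and for all 264 that passed. A test without moderation of the variance called 10 probe sets and a fit with array weights 609. Left out 1 at a time, the arrays mattered as follows: the count was 21 without KO 1, 89 without KO 2, 18 without KO 3, 59 without control 4, 150 without control 5 and 12 without control 6.

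Among the 12 genes with the largest rise, Hbb-bh1 came first, at 7.19 ± 0.46 in the knockout and 3.15 ± 0.48 in the controls (log2, n = 3 each, limma adjusted p = 0.00683). All 3 of its probe sets passed, with rises of 4.04, 3.76 and 3.06. Esm1, which encodes a proteoglycan secreted by endothelial cells, rose by 2.85 (SE 0.42). Chac1, an enzyme that degrades glutathione and is induced by the integrated stress response, rose by 2.30 (SE 0.28). Bcl11a, a transcription factor that represses embryonic and fetal globin genes, rose 3.51-fold, and both of its probe sets passed. The potassium channel gene Kcnj6 rose by 2.06 with 2 of its 5 probe sets past the threshold. Rises of 1.94 for the nucleolar protein gene Knop1, 1.76 for 1700017B05Rik, 1.68 for the zinc finger gene Zfp991 and 1.61 for the activin receptor gene Acvr2b followed. Adamdec1, a metalloprotease gene, rose by 1.52 and the RNA helicase gene Dhx8, a factor of pre-mRNA splicing, by 1.41. Itga9, the integrin alpha 9 gene, rose by 1.54 on 1 probe set and by 1.26 on another, while a further probe set of the gene was lower in the knockout at -0.85 with an adjusted p of 0.0488. Knop1 has a second probe set at -0.62, which did not pass (adjusted p = 0.0728). The other, brighter probe set of Zfp991 stood at 0.55 and did not pass (limma adjusted p = 0.142).

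Of the 12 genes with the largest fall, Rbm15 and Slc6a17 led, the latter at 3.84 ± 0.10 in the knockout and 7.02 ± 0.18 in the controls (log2, n = 3 each, limma adjusted p = 0.000335). Usp18, Rsad2, Gbp3 and Ifi27l2a, all induced by interferon, fell, with differences of -3.13, -2.42, -2.41 and -2.25. Dph5, an enzyme of the diphthamide modification of elongation factor eEF2, fell by 2.68 on 1 probe set, and its other, brighter probe set stood at 0.03 (adjusted p = 0.972). Ckmt2, the mitochondrial creatine kinase of striated muscle, went from 10.72 ± 0.22 in the controls to 8.59 ± 0.26, a 4.37-fold fall. Ftcd, an enzyme of histidine and folate metabolism, fell by 2.21, Cyp1b1, a cytochrome P450, by 2.20, and the glycerol channel gene Aqp7 by 2.25. Cyp1b1 and Aqp7 each passed on 1 probe set only. Saal1 fell by 2.28 on 1 probe set, while another was higher in the knockout by 0.68 (adjusted p = 0.0497). With single arrays left out, these 23 genes besides Rbm15 stayed past the threshold in 65 checks and not in 73, each time in the same direction. Esm1, Kcnj6, Adamdec1, Ifi27l2a and Cyp1b1 fell short whichever array was left out. Slc6a17, Knop1, Bcl11a, Dph5, Saal1 and Ftcd passed in each of these checks.

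**Figure D1:**
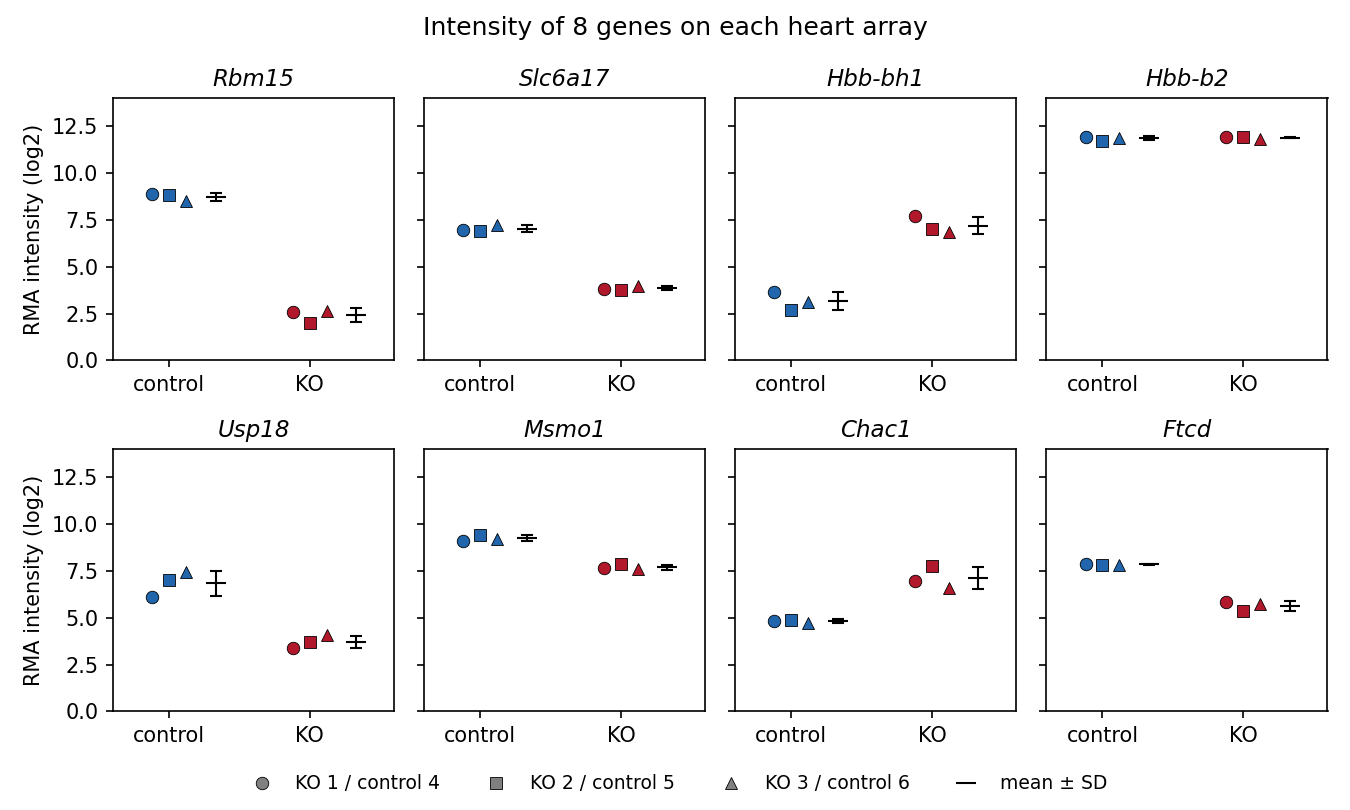
RMA intensity on the log2 scale (vertical axis) of 8 genes on each of the 3 control arrays (blue) and the 3 knockout arrays (red), with the group mean ± SD beside the points. Rbm15 lies at 8.72 in the controls and 2.42 in the knockout, and Hbb-bh1 at 3.15 and 7.19, while Hbb-b2 lies at 11.84 and 11.88.

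Genes of the interferon response were lower in the knockout hearts. All 32 measured members of the list lay lower, with a median difference of -1.04 on the log2 scale. Limma called 7 of them lower over all probe sets and 25 when adjusted over the list alone. Besides Usp18, Rsad2, Gbp3 and Ifi27l2a, the immunoproteasome subunit Psmb8 (-1.16), the RNA sensor Oas1a (-1.09) and the chemokine Cxcl10 (-1.36) fell. Ifit1 stood at -3.17 (SE 0.62) and did not pass over all probe sets (adjusted p = 0.0737). The mean of the list lay between -0.77 and -0.43 in the knockout arrays and between 0.21 and 0.88 in the controls, relative to each gene's mean (exact permutation p = 0.1, the smallest that 3 against 3 can give). Camera with a preset correlation gave an adjusted p of 1.43e-18, and adjusted p = 0.761 with an estimated correlation. Markers of macrophages and monocytes differed less, with a list mean of -0.18 (95% interval -0.63 to 0.27), while the list means of B cells, at -0.67, and of thymus and T cells, at -0.37, were also lower on each knockout array.

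Genes of cholesterol biosynthesis were also lower. All 19 measured members lay lower in the knockout, with a median of -0.55. By limma 4 passed over all probe sets, and 12 when adjusted over the list alone. Msmo1 (-1.53, SE 0.12), Cyp51 (-1.32), Idi1 (-1.27) and Fdps (-1.27) fell, which are enzymes of the mevalonate and sterol pathway. The sterol carrier gene Stard4 passed by its second probe set, which fell by 1.31. The list mean was -0.33 ± 0.04 in the knockout arrays and 0.33 ± 0.11 in the controls (n = 3 each). Camera gave an adjusted p of 3.9e-12 with the preset correlation, and adjusted p = 0.392 with an estimated correlation. Fry, which tests whether the members move 1 way on balance, gave 0.0186 after adjustment, the lowest of the 43 lists.

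In the list of the unfolded protein and integrated stress response 27 of 39 members lay higher, with a median of 0.13, and of 0.07 without control 6 (adjusted p = 0.0024). Chac1 passed over all probe sets, Mthfd2, a mitochondrial enzyme of folate metabolism, passed by its second probe set with a rise of 0.96, and 6 members passed when adjusted over the list alone. The latter included Phgdh at 0.93, the amino acid transporter Slc7a5 at 0.83 and Trib3 at 1.15. The transcription factor genes Atf4, at -0.06, and Ddit3, at 0.13, did not pass. Camera gave 0.000847 after adjustment with the preset correlation and adjusted p = 0.992 with an estimated correlation.

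The list of m6A methyltransferase components and readers, to whose complex Rbm15 belongs, had 12 of 14 members higher and a median of 0.18, and of 0.12 without KO 2 (adjusted p = 0.021). Limma called 0 of the 14 by their brightest probe sets over all probe sets, 5 passed an unadjusted p of 0.05, and the demethylase Alkbh5 at 0.59 passed when adjusted over the list alone. Dimmer probe sets passed for Ythdf1, a reader, which rose by 0.73, and for the complex member Wtap, which fell by 0.78, while the brightest probe set of Wtap stood at 0.33 (adjusted p = 0.179). The methyltransferase Mettl3 stood at -0.18. Camera gave 0.0015 after adjustment with the preset correlation, and adjusted p = 0.761 with an estimated correlation. Genes of the Spen family, nuclear export and splicing partners had a median of 0.01 (camera adjusted p = 0.242).

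Genes of oxidative phosphorylation lay slightly lower, with 71 of 75 members lower and a median of -0.12. Limma called 0 of them over all probe sets or over the list alone, and 2 passed an unadjusted p of 0.05, Sdhb at -0.29 and Cox7a1 at -0.38. The adjusted p was 0.000136 with the preset correlation and adjusted p = 0.992 with an estimated correlation. KO 2 had the lowest list mean, at -0.19, against -0.01 and 0.01 in the other knockout arrays, and without KO 2 the median was -0.05 (adjusted p = 0.022). KO 2 also had the largest 3' to 5' difference of the Gapdh control probe sets, at 1.21.

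The 4 lists of the cardiac muscle programme held 109 distinct measured genes, of which limma called 1 over all probe sets by its brightest probe set, and 7 higher and 10 lower passed an unadjusted p of 0.05. The called gene was Slc8a1, the sodium-calcium exchanger, with a rise of 1.01 (SE 0.14). Sarcomere and contractile proteins had a median of -0.10 (camera adjusted p = 0.137), with 24 members lower and 7 higher. Myoz2 stood at -0.31, Myh6 at -0.22 and Tnnt2 at 0.03. Medians were -0.03 for fetal and stress-responsive cardiac genes (0.975), 0.03 for cardiac transcription factors (0.975) and 0.01 for calcium handling, ion channels and gap junctions (0.605), each with its camera adjusted p. The smallest unadjusted p in the fetal list, with 8 members higher and 10 lower, belonged to Fhl2 (-0.29) and Hspb7 (-0.29). Among the transcription factors, with 19 higher and 14 lower, it belonged to Hand1 (-0.68) and Prox1 (-0.41). None of these genes passed over all probe sets. Fry's mixed test, which lets members go either way, passed for calcium handling (adjusted p = 0.000649) and cardiac transcription factors (0.012). It did not pass for sarcomere (0.146) or fetal and stress-responsive genes (0.184). The mixed test makes no comparison with genes outside the list, and 15.73% of all probe sets passed an unadjusted p of 0.05 in limma. Dimmer probe sets passed for Ldb3, a Z-disc protein gene, which fell by 1.10, for Myocd, a coactivator of serum response factor, which rose by 1.20, and for Trdn, a protein of the junctional sarcoplasmic reticulum, which fell by 0.89. The brightest probe sets of these genes stood at -0.01, 0.18 and -0.11.

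Lists of signalling pathways and cell types of the developing heart did not pass camera, which asks for a common direction. Fry's mixed test, which lets members go either way, passed for endothelium (adjusted p = 3.95e-05), valve (0.000167), mitosis (0.00271), Wnt (0.0117) and BMP and TGF-beta (0.0424). As it makes no comparison with other genes, these passes do not set the lists apart from the rest of the array. The Notch pathway had a median of 0.08 (camera adjusted p = 0.324), with 0 of 33 members called by limma and 1 higher and 1 lower at an unadjusted p of 0.05. The BMP and TGF-beta pathway had a median of 0.04 (0.696), and Smad3 rose by 1.11. In the Wnt pathway, with a median of 0.02 (0.605), the receptor gene Fzd4 rose by 0.82. Among valve and endocardial cushion genes, with a median of 0.04 (0.959), the tendon and valve transcription factor Scx rose by 0.82. The endothelium list had a median of -0.08 (0.396) and 2 called members, Esm1 and the lymphatic hyaluronan receptor Lyve1, which fell by 1.83. Both probe sets of Lyve1 passed. Foxm1, a transcription factor of mitosis, rose by 0.77 on 1 of its 4 probe sets, and the mitosis list had a median of -0.03 (0.975). The S phase list had a median of -0.10 (0.181).

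A further 12 lists did not pass camera. Medians and camera adjusted p were -0.03 and 0.975 for fatty acid uptake and oxidation, in which Acot1 rose by 1.05, 0.10 and 0.228 for hypoxia and glycolysis, and -0.07 and 0.366 for heat shock proteins. They were -0.04 and 0.906 for SRF and MRTF targets, 0.07 and 0.605 for p53 targets and apoptosis, and 0.01 and 0.762 for immediate early genes. Glucocorticoid-responsive genes had -0.07 and 0.605, and Klf9 passed by a dimmer probe set with a fall of 1.05. Ribosomal proteins had 0.03 and 0.125, extracellular matrix and fibroblasts -0.05 and 0.228, and imprinted genes 0.06 and 0.605, with Dlk1 lower by a fall of 0.72. Vascular smooth muscle and pericytes had 0.02 and 0.975, and epicardium and mesothelium -0.20 and 0.242. Fry's mixed test passed for imprinted genes (adjusted p = 0.000167), fatty acid uptake and oxidation (0.000521), vascular smooth muscle (0.00239) and extracellular matrix (0.00271). It also passed for p53 targets (0.0213) and glucocorticoid-responsive genes (0.0372), and not for the rest.

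Blood genes other than Hbb-bh1 showed no common rise. The erythroid list had a median of -0.14 and a mean of 0.01 (camera adjusted p = 0.762), and without Hbb-bh1 its 36 members had a median of -0.17, with 25 lower and 11 higher. The adult globin Hbb-b2 stood at 0.04 (SE 0.09). The other embryonic globins, Hbb-y at 0.51 (SE 0.73) and Hba-x at 1.05 (SE 0.63), did not pass. Their spread between control hearts was wide, with SDs of 1.48 and 1.39, while that of Hbb-bh1 was 0.48. In the controls Hbb-bh1 had a mean of 3.15, at the 17.4 percentile of all probe sets. A signal this low may limit its SD, so the SDs do not show that Hbb-bh1 was the steadier gene. Megakaryocytes and platelets had a median of -0.06 (camera adjusted p = 0.975), macrophages and monocytes -0.04 (0.228) and neutrophils, mast cells and myeloid progenitors -0.52 (0.181). Of these lists fry's mixed test passed for macrophages and monocytes (adjusted p = 0.00402), in which limma called 1 member lower.

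Liver genes differed between the controls more than between the groups, while the list means of thymus and of B cells did not overlap between the groups. The liver list mean was highest on control 4, at 2.11, and control 6, at 0.82, and lowest on control 5, at -1.53, with the knockout arrays at 0.01, -0.28 and -1.13 (exact permutation p = 0.5). Of 36 liver genes 35 lay lower in the knockout, with a median of -0.77, and limma called 0, with 3 at an unadjusted p of 0.05. Camera gave 0.00879 after adjustment with the preset correlation and adjusted p = 0.992 with an estimated correlation. With controls 4 and 6 both left out, a choice made after the data were examined, the liver median was 1.27 in the other direction. Albumin, the main product of the liver, was at 13.23 on control 4 and 10.07 on control 5, and Alb differed by -0.05 between the groups. B cells had a median of -0.59 (0.000308, and adjusted p = 0.992 with an estimated correlation) and 0 calls by brightest probe sets with 8 at an unadjusted p of 0.05, among them Pou2af1 at -2.67. Ms4a1 passed by its second probe set, with a fall of 0.66 near the floor of the arrays. Thymus and T cells had a median of -0.24 (0.0356, and adjusted p = 0.992 with an estimated correlation), with 0 calls and 8 at an unadjusted p of 0.05, 6 of them lower. Both lists were highest on controls 4 and 6, and their means lay lower on each knockout array than on each control, between -0.44 and -0.27 against -0.11 to 0.65 for B cells and between -0.22 and -0.16 against -0.13 to 0.48 for thymus (exact permutation p = 0.1 each). The thymus call was lost without KO 2 (median -0.31, 0.124), KO 3 (-0.28, 0.0719), control 4 (-0.27, 0.0745) or control 6 (-0.23, 0.144), and the liver call without KO 3 (median -0.49, 0.208), control 4 (-0.02, 0.777) or control 6 (-0.59, 0.144), while without control 5 the liver median was -1.84. With probe sets of a mean log2 of at least 6 only, the liver call was lost at a median of -0.80 (0.142). The B cell and thymus lists then kept fewer than 5 members each and were not tested, so they rest mostly on dim probe sets. With the Gapdh 3' to 5' difference as a covariate the thymus call (-0.24, 0.151) and the liver call (-0.63, 0.0758) were lost, and without controls 4 and 6 the B cell call was (-0.25, 0.0889), as was that of thymus (-0.07, 0.774).

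Lists of other tissues near the heart did not pass camera. Fry's mixed test passed for brown and white fat (adjusted p = 0.000521), neurons and Schwann cells (0.000521) and cartilage and bone (0.0128), and not for the rest. Lung epithelium had a median of -0.10 (camera adjusted p = 0.181), and Scgb1a1, a product of airway club cells, was at 6.79 on KO 3 and 6.44 on control 6 and at most 2.84 on the other arrays. Skeletal muscle had a median of -0.05 (0.975), and skin and squamous epithelium 0.01 (0.975). In cartilage and bone, with 0.07 (0.906), Comp fell by 1.87. In brown and white fat, with -0.15 (0.141), the desaturase Scd1 fell by 0.89. Among neurons and Schwann cells, with -0.04 (0.881), Dbh, an enzyme of noradrenaline synthesis, fell by 1.09. Sex-linked genes had a median of 0.03 (0.785), and Xist, the RNA of the inactive X chromosome, was above 9 on KO 1, KO 2, control 4 and control 6 and below 4 on KO 3 and control 5.

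**Figure D2:**
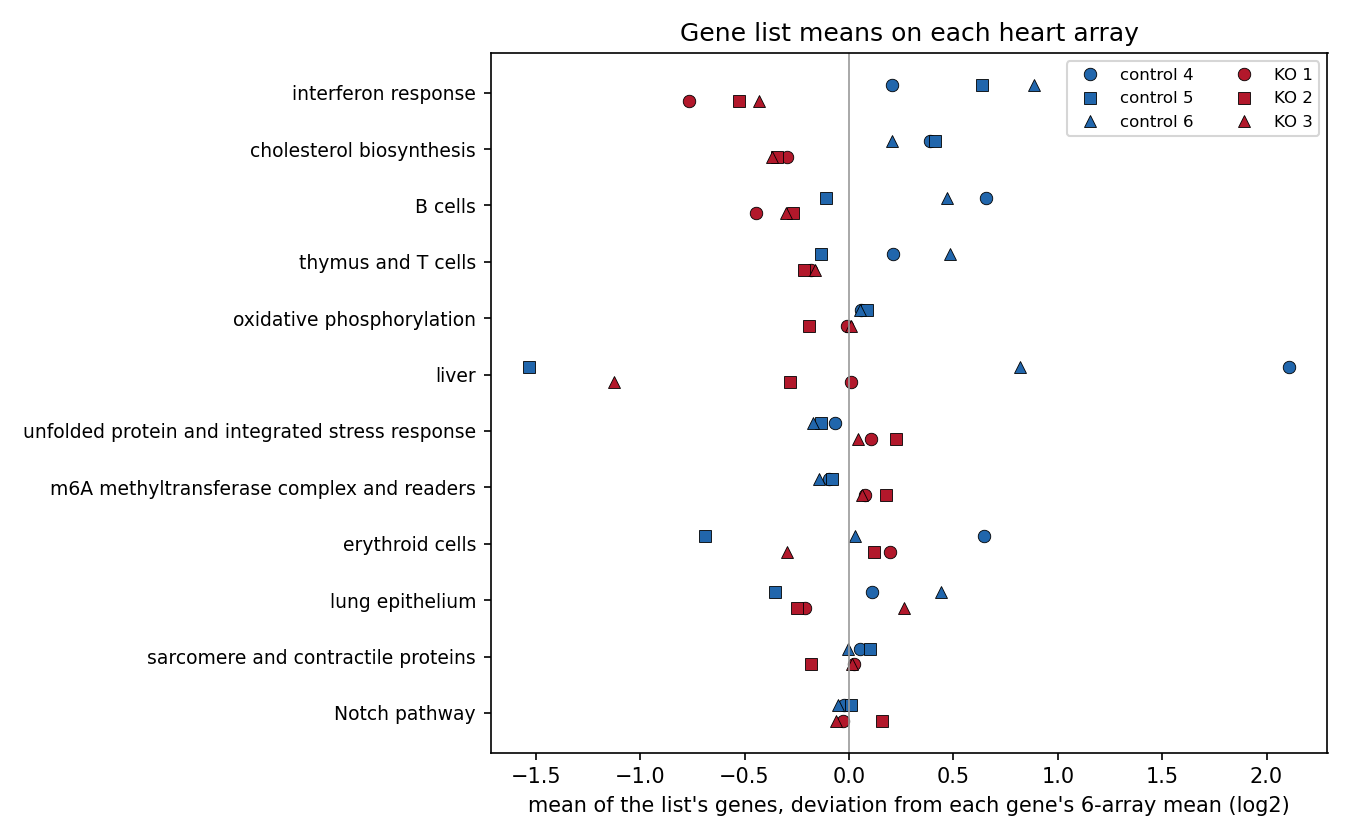
Mean over the genes of 12 lists on each control array (blue) and each knockout array (red), as the log2 deviation from each gene's mean over the 6 arrays (horizontal axis). The interferon list lies between -0.77 and -0.43 on the knockout arrays and between 0.21 and 0.88 on the controls, while the liver list spans -1.53 to 2.11 among the controls alone.

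Of the 43 lists, 8 passed camera with the preset correlation, 6 lower and 2 higher in the knockout, 0 passed with an estimated correlation, 1 passed fry's directional test, cholesterol biosynthesis, and 22 passed its mixed test. Other splits of the same 6 arrays put between 6 and 19 lists past the preset threshold of camera, so that its count alone does not set the genotypes apart. The mixed test was not repeated on other splits. It does not compare members with other genes, so its 22 passes do not show lists that differ more than the array as a whole. Of all probe sets, 15.73% passed an unadjusted p of 0.05 in limma. As a measure of RNA quality, the 3' minus 5' difference of the Gapdh control probe sets was 1.02 ± 0.17 in the knockout and 0.98 ± 0.09 in the controls (log2, n = 3 each, exact two-sided permutation p = 0.8), and that of Actb was 1.91 ± 0.08 and 1.91 ± 0.07 (exact p = 0.9). With 3 arrays a group this test cannot give a p under 0.1, so a difference in RNA quality is not excluded.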

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

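The liver score covariate, with and without its square, the fit without controls 4 and 6 and the Gapdh differences with arrays left out were chosen after seeing the data. The count of 264 probe sets was 10 without variance moderation, 609 with array weights, 154 with 1 probe set per gene, 133 with the mean of a gene's probe sets, 104 with Xist as a covariate and 4 without controls 4 and 6. In the last, control 5 alone is assumed to vary like the other arrays. The causes of these moves and of those of the lists below were not tested. With 1 array left out the count ranged from 12 to 150. Under the other settings it lay between 197 and 353. More probe sets were lower than higher in the main fit, but not with median centring (156 higher, 146 lower) or quantile normalisation (139 higher, 136 lower). Rbm15 passed under every setting in which it was tested, from -6.42 to -6.10 with 1 array left out. The filters on low values removed its probe set. The 8 lists became 0 with an estimated correlation, 1 with fry's directional test and 22 with its mixed test, and 6 to 9 under the other settings with all arrays. With 1 array left out they were 7 to 15, the highest without control 5. Without controls 4 and 6 they were 11, and the liver list turned to 1.27 (camera adjusted p = 3.37e-09), where control 5, the array with the lowest liver score, is the only control. The Gapdh difference ranged from -0.06 to 0.09 with 1 array left out. The 23 other named genes kept their call in 308 of 442 checks, fell short in 134 and reversed in 0. Lists kept it in 103 of 134 checks, fell short in 30 and reversed in 1. Cholesterol biosynthesis failed only with the estimated correlation, and the interferon list with that and fry's directional test. No paired analysis was possible because the groups share no replicate numbers. Signal near the background floor limits Rbm15, Aqp7 and other dim probe sets, and 3 arrays a group limit the rest.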

Other observations

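The tests of macrophages, of the liver range, of the squared liver score and of neighbouring genes, and the liver score and the fit without controls 4 and 6, were chosen after the results were seen, as were the genes in the next paragraphs that the rule did not take.

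Some genes chosen after their values were seen are given here without a test of a common theme, and the endothelium list did not pass camera (adjusted p = 0.396). Esm1, a marker of endothelial tip cells, rose by 2.85 from a low level of 3.26, and fell short with any 1 array left out. Lyve1, on lymphatic endothelium and resident macrophages, fell by 1.83. Cldn5, a tight junction gene of endothelium, stood at -1.10 and did not pass (adjusted p = 0.0762). Bcl11a, a repressor of embryonic globins, and Hbb-bh1 were both higher on all 3 knockout arrays. Zfpm1, the cofactor of GATA1, rose by 0.64 on 1 probe set. Cbfa2t3, a corepressor in blood progenitors, fell by 1.23 and 0.65 on 2 probe sets and stood at 0.02 and -0.04 on 2 others. The growth factor gene Fgf16 of the embryonic heart fell by 0.92 at a low level, from 3.53 to 2.61.

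In some genes called probe sets went opposite ways. Of 23 genes with at least 2 called probe sets, 5 had calls in both directions, namely Abhd6, Chid1, Itga9, Saal1 and Usp48. Other splits gave 0 such genes, but they called at most 1 probe set and so could not have shown any. Abhd6 stood at 0.93 and -1.39, Chid1 at 1.40 and -0.99, and Usp48 at 1.07 and -0.80.

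The real grouping of the 6 arrays called 264 probe sets, and the highest of the other 9 groupings called 1, so that only the real one, 1 of 10, gave as many. For the gene lists the real grouping put 8 past the threshold and the highest other 19, and 9 of 10 groupings gave at least as many. With 10 groupings a share under 0.05 cannot be reached.

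Interferon genes were lower in all 3 knockout arrays, by a list mean of -1.15 (95% interval -1.77 to -0.54). Differing amounts of liver tissue are argued against, since with the liver score held equal the mean was -1.17 (-1.90 to -0.45), and control 5, with the lowest score, and control 4, with the highest, both lay above each knockout array, at 0.64 and 0.21. By list means, fewer macrophages alone are argued against too, since the macrophage list differed by 0.97 less (0.22 to 1.73). Of its 31 members limma called 1 lower over all probe sets and 2 over the list alone. Whether some macrophages only were fewer was not tested. The B cell list, with a mean difference of -0.67, and the thymus list, with -0.37, were also lower on each knockout array. Both lists rest mostly on probe sets with a mean log2 under 6. Whether fewer lymphoid cells go with the interferon fall was not tested. An effect of the genotype and an exposure that differed between the groups stay open and untested, as the labels give neither litter nor batch, and control and knockout littermates handled together would decide between them.

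Liver genes were lower in the knockout by a list mean of -0.93, against a range of 3.64 within the controls, and the genes moved together within groups (median correlation 0.98 over 27 genes, across 6 arrays). Differing amounts of liver RNA unrelated to genotype could account for this. With the liver score held equal on a straight line 15 of 31 members outside the score passed over the list, all lower. But this decides nothing, since all 3 knockout scores lie between those of the controls. A curved relation to the amount could give such falls. With the square of the score held equal as well, 8 passed over the list, all lower, 5 of them with a mean log2 of at least 6, namely Fabp1 (-2.24, SE 0.20), Ahsg (-1.09), Serpina1c (-1.14), Rbp4 (-0.84) and Cps1 (-0.88). Over all probe sets these 5 genes did not pass (limma adjusted p from 0.0975 to 0.355). On 6 arrays, a fit of genotype, score and square leaves little to judge the spread by. As liver genes move together, the 5 are not separate observations either. Amount alone therefore stays open for all members.

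Near Rbm15, 4 other genes changed among the 100 measured genes within 50 places on either side, namely Slc6a17, 2 places away, Amigo1, Prmt6 and Dph5. As many changed genes lay in 9.01% of 10166 windows elsewhere, so that chance placement could account for the count. The count takes no account of the size of a change or of its closeness to Rbm15. It therefore does not test whether the fall of Slc6a17, at -3.17, lies beside Rbm15 by chance. A local effect on adjoining genes only cannot be told apart from this, since 3 of the 4 lie more than 5 places away, a number that 18.8% of the windows elsewhere reach. Slc6a17 may be a local effect of the null allele or of strain DNA linked to it, and the strains are not given in the sources used here.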
